A study of Mus musculus with 3 samples.

How the data were processed

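The series holds 3 messenger RNA sequencing libraries of 4T1 cells, an established mouse mammary carcinoma line, made to over-express WISP2. Per the labels' protocols, total lysates were extracted with a spin-column kit and libraries were made with a strand-preserving poly(A) kit; tumour cells had been transduced with packaged vector and selected with puromycin. That protocol describes constructs of Wisp1 and not the WISP2 construct. The deposited table gives, for each gene symbol, a whole-number read count per library that was not normalized, per the file headers and the values themselves. The authors' processing named CASAVA 1.7, BWA, STAR and HTSeq and the mouse build mm9, per the submitters' processing notes, which give no role or order. The gene annotation, the strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here. Genes with near-identical copies or processed pseudogenes (Hspa1a and Hspa1b, Eef1a1, Rpsa, Npm1, Ppia and Gapdh, for example) therefore have uncertain levels, as do overlapping genes.

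The table has 34591 rows and 3 count columns, and all of its rows name a gene. The column names match no sample title, so the columns were assigned to the over-expression group as a whole, because each sample's description names this table and the group has 3 samples; the libraries are called C1, C2 and C3 after the column suffixes, which carry no order. All 3 libraries belong to 1 group. The empty-vector control libraries named in the series' design text were not used here, so no effect of WISP2 over-expression was estimated and no test between groups was made. No source says whether the 3 libraries came from separate cultures, so every measure of spread covers the difference between these samples, which may be technical.

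Levels were expressed as CPM, each count scaled by the total of gene-assigned counts of its library, and are given as mean ± SD over 3 libraries. CPM is not corrected for transcript length, so a ratio between 2 genes was also computed after division by the exon length of GENCODE M21, which gave a length for 31427 of the 34591 symbols (90.8%) and for 11535 of the 11700 genes at 1 CPM or more in every library. That annotation is on another genome build than the one the submitters name, so it was used for lengths and GC content only and no coordinates are given. Ratios between 2 genes were taken within each library with 0.5 counts added to each; an exact two-sided sign-flip test over 3 libraries cannot go below p = 0.25, so none is reported. Intervals on single libraries are exact 95% binomial (Clopper-Pearson) intervals, and a gene at 0 is given the limit set by 3 counts. These intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules.

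The depth was 17630755 counts in C1, 67028365 in C2 and 47577315 in C3, so 1 count was worth 0.0567, 0.0149 and 0.0210 CPM. Spread between the libraries was measured with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) on the counts, with TMM scaling, the filterByExpr filter (13026 genes) and an intercept-only model. Each gene was tested against counting noise with a Poisson dispersion test (chi-square, 2 degrees of freedom) and against genes of similar level with the ratio of its quasi-likelihood dispersion to the trended prior (F test), both with Benjamini-Hochberg adjustment at 0.05. On simulated libraries of 13026 genes with Poisson counts only, both tests called 0 genes. With negative binomial counts at the fitted trend and 200 genes changed in 1 library, the F test recovered 55.0% of those changed by 1.5-fold, 71.0% of those changed by 2-fold and 85.5% of those changed by 3-fold, and called no unchanged gene. The simulated genes had no spread of their own around the trend, so these rates and the absence of false calls may not hold for the data.

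Before the data were examined, 29 gene lists (329 entries, 320 different genes, all present in the table), the gene pairs, the tests and the alternatives were fixed. For each list the median log2(CPM + 1) was placed among 10000 random lists of the same size drawn from all genes with a count, and the median deviation of each library from the gene's mean was placed among 10000 random lists matched on mean expression over 50 abundance bins. Members with 0 counts in all libraries stayed in the level median, whereas the random lists held no such gene. The level percentiles of lists with such members are therefore lowered in part by construction. These percentiles describe the libraries; genes are not independent replicates and genes of a list vary together, so no p-value was attached. The genes named are the CCN family, the genes of the preset pairs, the 4 most abundant members of each list and up to 3 of its members at 0, the 10 most abundant genes, and up to 10 genes past the threshold of the F test; a few genes that this rule names are not reported here. Alternatives covered library scaling (TMM, DESeq2 1.42.0 size factors, totals without abundant genes), filters, pseudocounts, length correction, a robust fit, DESeq2 dispersions and leaving out each library.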

Results

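RNA sequencing was carried out on 4T1 cells, a mouse mammary carcinoma line, that over-expressed WISP2, a secreted matricellular protein of the CCN family. One group of 3 libraries was measured. The study's title concerns WISP2, collagen linearization and metastasis, and its design text sets these cells against empty-vector controls, which were not analysed here. The data therefore describe the expression state of the over-expressing cells and the spread between their libraries, and not a change caused by WISP2. The libraries held 17630755 (C1), 67028365 (C2) and 47577315 (C3) counts. In every library 11700 genes reached 1 CPM, and 15794 of the 34591 symbols had no count in any library. The most abundant gene was that of the elongation factor Eef1a1, at 12048 ± 249 CPM (SD, n = 3), followed by the chaperone Hsp90ab1 at 5830 ± 91.9 CPM, the galectin Lgals1 at 5196 ± 191 CPM, the elongation factor Eef2 at 4313 ± 108 CPM and Pabpc1, which binds poly(A) tails, at 4065 ± 62.1 CPM. The glycolytic enzyme Pkm2 (3678 ± 126 CPM), Actb (3436 ± 245 CPM), the nucleolar genes Npm1 (3299 ± 152 CPM) and Ncl (3156 ± 77.7 CPM) and the ribosomal gene Rpsa (3109 ± 25.7 CPM) completed the 10 most abundant genes, which together took 4.81% ± 0.03 of counts. Mitochondrial genes took 0.551% ± 0.014.

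Wisp2 was the most abundant member of its family in each library. It stood at 422 ± 35.4 CPM (SD, n = 3), above 97.0% of the genes detected at 1 CPM or more, and 351 genes were higher. The single libraries gave 429 CPM in C1 (95% interval 419 to 438), 384 CPM in C2 (379 to 389) and 454 CPM in C3 (448 to 460). Cyr61 (252 ± 48.7 CPM) and Ctgf (206 ± 29.1 CPM), immediate targets of the YAP and TAZ coactivators, followed, and Wisp1, the paralog of Wisp2 for which the labels' protocol describes constructs, stood at 53.6 ± 7.70 CPM. Nov was near the detection floor at 0.956 ± 0.054 CPM. Wisp3 had 0 counts in all libraries, which allows up to 0.170 CPM in C1, 0.0448 CPM in C2 and 0.0631 CPM in C3.

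Within libraries, Wisp2 exceeded Wisp1 by 2.98 ± 0.31 on the log2 scale (7.91-fold), Ctgf by 1.04 ± 0.12 (2.06-fold) and Cyr61 by 0.76 ± 0.16 (1.69-fold), in 3 of 3 libraries each. Division by exon length raised the ratio of Wisp2 to Wisp1 to 22.9-fold, that to Ctgf to 3.06-fold and that to Cyr61 to 1.77-fold. Gene-level counts do not separate reads of the introduced gene from reads of the endogenous one, and the species, untranslated regions and length of the introduced WISP2 transcript are not given in the sources used here. The Wisp2 values therefore hold reads of the introduced gene only as far as these match the annotated mouse gene.

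**Figure D1:**
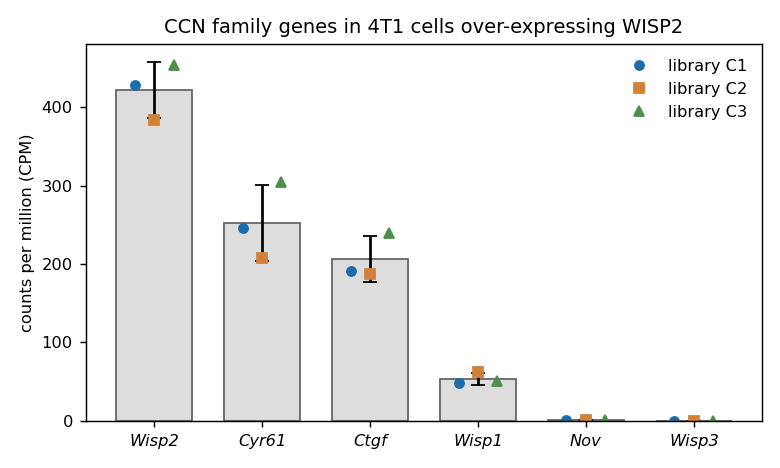
Level in CPM of the CCN family genes in the 3 libraries of WISP2 over-expressing 4T1 cells. Bars are means, error bars are SD (n = 3) and symbols are single libraries; Wisp2 lies between 384 and 454 CPM, above every other member.

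Of the genes that build the collagen matrix, basement membrane components were abundant and fibrillar collagens were nearly absent. Among 11 chains of fibril-forming collagens only Col5a1, a chain of collagen V, reached 1 CPM in every library (59.7 ± 3.61 CPM). Col27a1 (0.956 ± 0.321 CPM), Col1a2 (0.899 ± 0.074 CPM) and Col11a2 (0.821 ± 0.324 CPM) had few counts, and Col11a1 had none. Col1a1, a chain of collagen I, lay 0.27 ± 0.42 on the log2 scale below Col1a2, the other collagen I chain; the difference was smaller than its SD and changed sign after length correction. Of 19 basement membrane genes 13 reached 1 CPM and 8 exceeded 100 CPM, among them the laminin chains Lama5 (505 ± 12.4 CPM) and Lamb1 (471 ± 23.9 CPM) and the collagen IV chain Col4a1 (426 ± 5.50 CPM). Col4a3, Lama1 and Lama4 had 0 counts. The small leucine-rich proteoglycans, which bind collagen fibrils, were all below 1 CPM: Ogn stood at 0.357 CPM, Bgn at 0.196 CPM, Aspn at 0.0269 CPM and Prelp at 0.0259 CPM on average, and 4 of 9, including Fmod, Lum and Kera, had 0 counts. Of 13 matricellular genes outside the CCN family 6 reached 1 CPM, led by Thbs1 (1079 ± 78.6 CPM), Sparc (299 ± 16.0 CPM), Spp1 (223 ± 20.2 CPM) and Postn (12.1 ± 2.23 CPM), and Thbs4 had 0 counts. The basement membrane list lay at the 98.8th percentile of random lists, but at the 76.8th when counts were divided by exon length. The fibrillar collagen list lay at the 8.96th percentile, or the 0.98th after length correction, and the proteoglycan list at the 0.01st. Both lists kept their members at 0 counts (1 of 11 and 4 of 9), which the random lists could not hold, so these percentiles are biased low.

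The enzymes that modify and cross-link collagen were largely expressed. Of 20 such genes 17 reached 1 CPM in every library: P4hb, the protein disulfide isomerase subunit of prolyl hydroxylase, stood at 642 ± 53.7 CPM, Serpinh1, the collagen chaperone, at 465 ± 6.30 CPM, the lysyl oxidase Loxl4 at 224 ± 17.6 CPM and the procollagen proteinase Bmp1 at 211 ± 26.6 CPM. Adamts2 had 0 counts. Lox itself had 2 counts summed over the libraries against 106 for Loxl2, a ratio of Loxl2 to Lox of 53.0 (95% counting interval 14.3 to 443). The geometric mean within libraries was 31.0-fold, and 27.4-fold after length correction. Lox and Loxl2 were thus both close to the floor while Loxl4 was not. Among collagen receptors the integrin chain Itgb1 (1208 ± 69.2 CPM), Cd44 (421 ± 40.0 CPM), the discoidin domain receptor Ddr2 (250.0 ± 25.8 CPM) and Sdc1 (166 ± 16.6 CPM) were highest. The integrin chain Itga2 exceeded Itga1 by 5.80 ± 0.32 on the log2 scale (55.7-fold, or 145-fold after length correction), and Itga11 and Gp6 had 0 counts.

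Of 18 matrix metalloproteinases 6 were at 1 CPM or more in all libraries, led by the membrane-bound Mmp14 (144 ± 7.16 CPM), the gelatinase Mmp9 (91.5 ± 48.8 CPM), Mmp11 (17.3 ± 1.66 CPM) and Mmp3 (13.1 ± 2.34 CPM). Mmp7, Mmp16 and Mmp25 had 0 counts. Mmp2, the other gelatinase, had 18 summed counts against 19300 for Mmp14, a 1072-fold ratio (95% counting interval 678 to 1809.6); the geometric mean within libraries was 1222-fold, and 691-fold after length correction. Of their inhibitors, Timp2 (369.9 ± 4.55 CPM) exceeded Timp1 (63.4 ± 3.02 CPM) by 5.84-fold, a ratio that shrank to 1.33-fold after length correction. Timp3 averaged 0.157 CPM and Timp4 had 0 counts. The metalloproteinase list lay at the 6.41st percentile of random lists, and at the 1.83rd after length correction. It kept its 3 members at 0 counts, which the random lists could not hold, so these percentiles are biased low.

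The libraries carried an epithelial program together with part of a mesenchymal one. All 17 epithelial genes reached 1 CPM, with the keratins Krt8 (1077 ± 80.8 CPM), Krt18 (986 ± 65.1 CPM) and Krt7 (945 ± 33.6 CPM) and the cadherin Cdh1 (444 ± 17.1 CPM) highest. Of 14 mesenchymal genes 7 did so: the intermediate filament gene Vim stood at 2493 ± 150 CPM, fibronectin, Fn1, at 1734 ± 188 CPM, S100a4 at 625 ± 92.3 CPM and Itga5 at 58.9 ± 3.58 CPM, whereas the transcription factors Snai2 and Twist2 had 0 counts. Vim exceeded Cdh1 by 2.49 ± 0.10 on the log2 scale (5.62-fold). Cdh2, the cadherin of mesenchymal cells, had 7 summed counts against 59251 for Cdh1, a ratio of 8464 (95% counting interval 4108 to 21054); the geometric mean within libraries was 6437-fold, and 11352-fold after length correction. The epithelial list lay at the 99.95th percentile and the mesenchymal list, which kept its 2 members at 0 counts, at the 28.6th.

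Mammary lineage markers were few. Of the basal list only Krt14 (64.5 ± 2.65 CPM) reached 1 CPM; Krt17 (0.165 CPM), Trp63 (0.159 CPM) and Acta2 (0.129 CPM) did not, and Krt8 was at least 6100-fold above Krt5, which had 0 counts, with a floor of 3 counts per library. Of the luminal list the transcription factors Gata3 (62.4 ± 3.01 CPM) and Foxa1 (2.04 ± 0.164 CPM) and the estrogen receptor gene Esr1 (10.4 ± 1.31 CPM) reached it, Prlr had 2 counts, and Elf5, Kit and Wap had none. In the preset lists of endothelial, fibroblast, leukocyte, erythroid, adipocyte and muscle markers, only Pdgfra, Lyz2 and Cd68 reached 1 CPM in every library. Endothelial markers were all below 1 CPM (Pecam1 0.0899 CPM, Emcn 0.0567 CPM, Kdr 0.0239 CPM and Cdh5 0.0120 CPM on average). Of the fibroblast list only Pdgfra was detected (18.3 ± 1.03 CPM); Col3a1, Dcn and Pdgfrb had between 1 and 3 summed counts, and Lum and Thy1 had 0. Fabp4, Adipoq and Ckm had at most 4 summed counts, and Hba-a1, Hbb-b1 and Alas2 had 0. Leukocyte markers were uneven. Lyz2, the macrophage lysozyme, stood at 9.42 CPM in C1 against 3.12 in C2 and 3.78 in C3. Emr1 stood at 1.76 against 0.343 and 0.462, Csf1r at 1.42 against 0.642 and 0.778, and Cd68 at 5.56 against 5.15 and 4.27. Also highest in C1, and named after their values were seen, were Laptm5 (1.13 against 0.209 and 0.336), Itgam (0.567 against 0.149 and 0.189) and Tyrobp (0.227 against 0.104 and 0.147). Of the markers with a count only Ptprc was not highest there, with 1, 8 and 13 counts (0.0567, 0.119 and 0.273 CPM). Ptprc is expressed by leukocytes in general and was likewise named after its values were seen. Cd3e had 0 counts. Xist averaged 0.825 CPM (1.42 in C1, 0.552 in C2 and 0.504 in C3), and Ddx3y, Kdm5d and Eif2s3y had 0 counts.

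**Figure D2:**
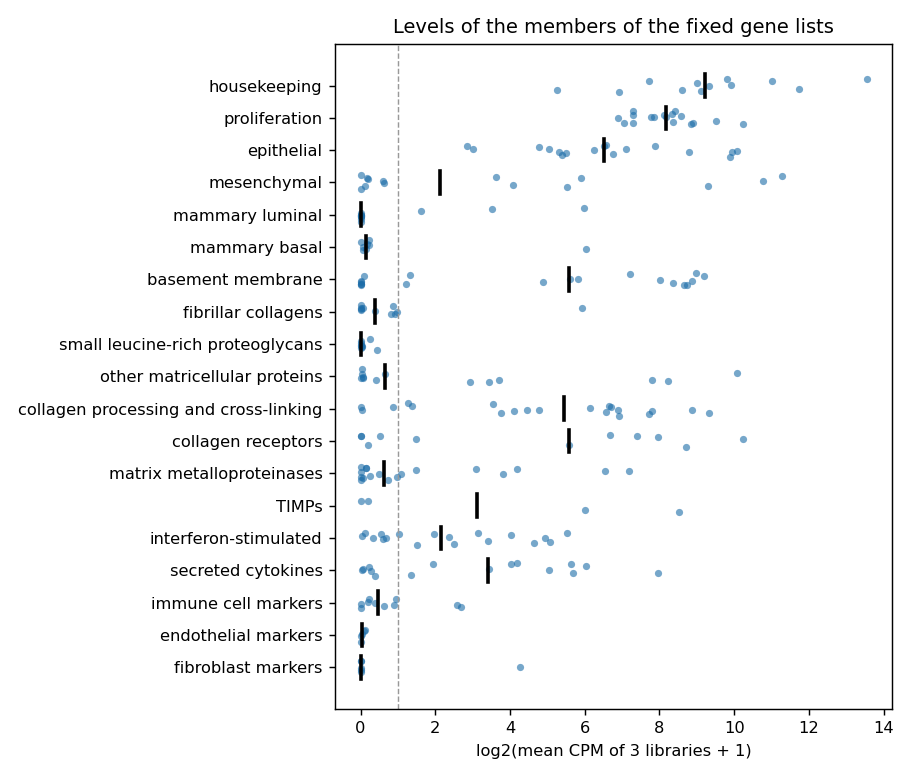
Mean level of each member of the fixed gene lists, as log2(CPM + 1) averaged from 3 libraries. Points are genes, black bars are list medians and the dashed line marks 1 CPM; all 17 epithelial and all 17 proliferation genes lie to its right, whereas only 1 of 11 fibrillar collagens does.

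The YAP and TAZ, TGF-beta and proliferation lists were at high levels, at the 99.97th, 99.93rd and 100th percentiles of random lists, and the Wnt list was intermediate, at the 68.8th. All 8 YAP and TAZ targets were detected, with the receptor tyrosine kinase Axl at 1035 ± 23.2 CPM and Ankrd1 at 240.2 ± 10.5 CPM beside Cyr61 and Ctgf, which this list shares with the CCN family. All 16 TGF-beta pathway genes were detected, led by the latency proteins Ltbp3 (280.2 ± 44.1 CPM) and Ltbp1 (245 ± 6.63 CPM), the receptor Tgfbr2 (187 ± 6.34 CPM) and Skil (147 ± 9.63 CPM). Of 12 Wnt pathway genes 8 were detected, led by Ctnnb1 (975 ± 16.3 CPM), the coreceptors Lrp5 (182 ± 15.8 CPM) and Lrp6 (93.9 ± 4.21 CPM) and by Fzd6 (126 ± 5.64 CPM), while the feedback targets Axin2 and Nkd1 had 0 counts. All 17 proliferation genes exceeded 100 CPM, with Top2a at 1203 ± 43.1 CPM, Mki67 at 724 ± 41.7 CPM, Ccna2 at 478 ± 26.6 CPM and Mcm6 at 454 ± 19.1 CPM. The proliferation list and the housekeeping list, the latter led by Eef1a1, Actb, Rplp0 (2067 ± 88.9 CPM) and Ppia (972 ± 11.5 CPM), lay above all 10000 random lists.

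Interferon-stimulated genes reached 1 CPM in 11 of 18 cases, and none exceeded 100 CPM. Ddx58 at 44.8 ± 1.39 CPM, Bst2 at 32.4 ± 1.31 CPM and Ifit2 at 29.6 ± 4.33 CPM were highest. Their list lay at the 26.39th percentile of random lists, or the 24.45th after length correction, so its level was not set apart from theirs. Of 15 secreted cytokines 10 reached 1 CPM, led by Csf1, the macrophage growth factor, at 249 ± 9.70 CPM, Lif at 64.2 ± 8.97 CPM, Cxcl16 at 50.2 ± 5.79 CPM and Vegfa at 48.2 ± 6.01 CPM. All 12 hypoxia genes were detected, with Ldha at 2075 ± 104 CPM, Pgk1 at 509 ± 7.95 CPM, Ndrg1 at 344 ± 73.4 CPM and P4ha1 at 117 ± 10.5 CPM. All 11 ER stress genes were detected, with the chaperones Hspa5 (2141 ± 89.1 CPM) and Hsp90b1 (1073 ± 11.9 CPM), the transcription factor Atf4 (319 ± 30.0 CPM) and its target Asns (271 ± 45.5 CPM) highest. Of the heat shock and immediate early lists, Hsph1 (280.2 ± 23.3 CPM), Dnajb1 (48.2 ± 2.22 CPM), Hspa1b (43.6 ± 5.54 CPM) and Hspa1a (7.87 ± 1.14 CPM), and Junb (112 ± 18.0 CPM), Jun (79.0 ± 10.9 CPM), Ier2 (37.2 ± 4.29 CPM) and Atf3 (12.4 ± 2.23 CPM), were highest.

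The 3 libraries were close to one another but not identical. Over the 11700 detected genes the Pearson correlation of log2(CPM + 1) across genes, which are not independent replicates, was 0.9977 for C1 and C2, 0.9973 for C1 and C3 and 0.9969 for C2 and C3. Between 10 and 11 of these genes differed over 2-fold in any pair of libraries. Each pair differed by more than sampling noise (chi-square per degree of freedom 4.08, 4.63 and 14.9 for the same pairs), so no library was merely a resampling of another. Technical copies of the same RNA with spread of their own are not excluded. The chi-square measure grows with depth, and C2 and C3 were the deepest libraries. The median absolute log2 difference was closer between pairs, at 0.0713, 0.0774 and 0.0886. The common biological coefficient of variation was 0.0571. Of 13026 genes 5118 (39.3%) varied more than counting noise allows (Poisson dispersion test, Benjamini-Hochberg 0.05). This count was 4908 without C1, 1761 without C2 and 1667 without C3. Each of these settings leaves fewer libraries and counts.

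Against genes of similar level, 9 genes stood out in spread (edgeR quasi-likelihood F test), and C3 held the most deviant value for 8 of them. Of 13026 genes tested, 671 had an unadjusted p under 0.05 in that test, close to the share expected by chance. The prior of the test was estimated from these same genes, which favours such a share. The share therefore does not show that spread around the trend was at chance level. Mmp9 stood at 147 CPM in C3 against 69.3 in C1 and 57.8 in C2 (adjusted p = 0.00154). The hyaluronan synthase Has2 (151 against 96.8 and 91.9), the zinc importer Slc39a10 (149 against 90.2 and 91.2), the laminin chain Lama3 (74.7 against 50.7 and 40.3) and the hypoxia-induced carbonic anhydrase Car9 (55.7 against 32.4 and 30.3) were also highest in C3, with adjusted p of 0.0267, 0.0267, 0.0267 and 0.0298 in the edgeR test. Lowest in C3 were the metallothionein Mt2 (15.5 against 41.7 and 41.0; adjusted p = 0.00615), the cystine transporter Slc7a11 (26.8 against 43.4 and 65.6; 0.00703), the pseudokinase Trib3 (27.0 against 38.3 and 57.0; 0.0267) and the alanine aminotransferase Gpt2 (46.8 against 67.2 and 87.1; 0.0267). Without C3 the test called 3 genes (Lyz2, mmu-mir-689-2 and mmu-mir-2134-4, named after their values were seen) and none of these 9, without C1 it called 52 including all 9, and without C2 it called 25 including 8. A robust fit called 0, with 588 genes at an unadjusted p under 0.05. That fit lowers the prior degrees of freedom of outlying genes, here to at most 0.277 for the 9. The median over all genes in the robust fit was 12.1, and the fit that was not robust gave 9.16.

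**Figure D3:**
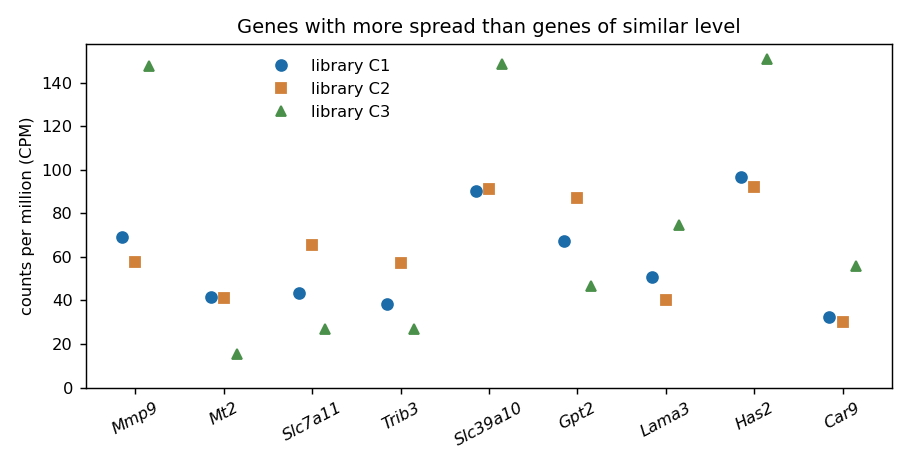
Level in CPM, in each library, of the 9 genes whose spread exceeded that of genes of similar level (edgeR quasi-likelihood F test, Benjamini-Hochberg 0.05). Symbols are single libraries; Mmp9 reaches 147 CPM in C3, and Mt2 stands at 15.5 CPM there.

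Members of several lists deviated together. Relative to each gene's mean, the hypoxia list had a median of 0.20 on the log2 scale in C3 (above all matched random lists), -0.12 in C2 and -0.09 in C1. The ER stress list had a median of 0.15 in C2 and -0.11 in C3. The members of that list that varied most were Trib3, Asns and Chac1, which are ATF4 targets, and not its chaperones. In the F test 1 of 12 hypoxia genes passed over all genes and 8 adjusted over the list alone; for ER stress these counts were 1 and 6 of 11, for the CCN family 0 and 4 of 5, and for the TGF-beta pathway 0 and 4 of 16. The collagen processing list (0.12), the epithelial list (0.10) and the immediate early list (0.13) were highest in C3, and the leukocyte list was highest in C1 (0.31); in the F test these had 0 genes passing over all genes and, adjusted over the list alone, 0 of 18, 0 of 17, 3 of 8 and 2 of 4 tested. The proliferation and housekeeping medians lay between -0.03 and 0.02 in each library. In all, 17 of 29 lists had a median outside the central 95% of matched random lists in at least 1 library, where chance with independent genes gives an expected count of at most 4.35; 1 of the 17, Xist with the Y-linked genes, rests on Xist alone.

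**Figure D4:**
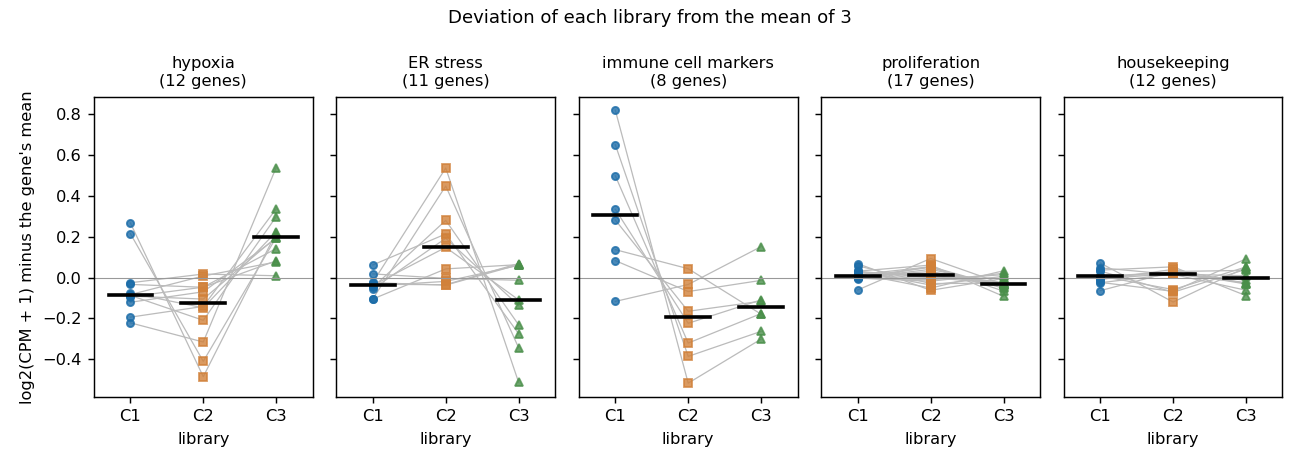
Deviation of log2(CPM + 1) in each library from the gene's mean over the 3 libraries, for 5 lists. Symbols are genes with a count, grey lines join the values of 1 gene and black bars are medians; the hypoxia median is 0.20 in C3, the ER stress median 0.15 in C2 and the leukocyte median 0.31 in C1.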

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

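Over 132 named genes with a count, other scaling (TMM or DESeq2 size factors) moved a level by at most 0.48%. Leaving out 1 library moved it over 1.5-fold for 18 of 31 genes with a mean below 1 CPM and for 1 of 101 at 1 CPM or more, Lyz2 (5.44 CPM, and 3.45 CPM without C1); Mmp9 fell from 91.5 to 63.5 CPM without C3. Leaving out each library gave a Wisp2 level of 406 to 441 CPM, a log2 ratio of Wisp2 to Wisp1 of 2.89 to 3.16, 11748 to 11761 detected genes, a coefficient of variation of 0.0415 to 0.0697, 9 to 10 lists above the central 95% of random lists (9 with all libraries), 1667 to 4908 genes more variable than counting noise, and 3 to 52 genes more variable than genes of similar level. Division by exon length moved the log2 ratio of Wisp2 to Wisp1 from 2.98 to 4.52, by construction, since the annotated exons of Wisp1 together are longer (5565 bases against 1924). These lengths join all annotated exons of a gene, and an expressed transcript may be shorter. The median gene-wise dispersion of DESeq2 gave a coefficient of 0.0342 against 0.0571; it summarises genes by a median and not by a shared likelihood. The count of 9 genes more variable than genes of similar level was the least stable result: 14 with library totals and no scaling factor, 171 when every gene with a count was tested, 3 with a floor of 10 CPM and 0 with the robust fit. The 9 genes were all among the 14 and the 171, and the 3 were among the 9; the cause of the rise to 171 was not tested. The number of lists with a deviant library was 17 with TMM, 17 of 20 lists when only detected members were used, and 18 with a pseudocount of 0.25; this last alternative, and a library size without mitochondrial genes, were chosen after seeing the data. No paired analysis was possible because the series has 1 group. Depth limits the genes below 1 CPM: a gene at 0 counts is bounded only at 0.170 CPM in C1.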

Other observations

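The patterns below were noticed in the spread between libraries. The tests on gene sets and the corrections for GC content and length were set, with their bounds, before their values were seen; the test of depth for Lyz2 and Lpl was chosen after the levels were known. No biological explanation from the design was tested, since the libraries carry no label beyond their group.

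Targets of ATF4 in the amino acid response and genes of glycolysis moved in opposite directions between C2 and C3. Psat1, of serine synthesis, stood at 810 CPM in C2 and 681 in C3, the asparaginyl-tRNA synthetase Nars at 543 and 461, and the stress sensor Sesn2 at 15.9 and 9.10. The glycolytic genes Aldoa (1109 in C2 and 1245 in C3), Gpi1 (432 and 508) and Tpi1 (810 and 898) went the other way. Of 11 antioxidant NRF2 targets 9 were lower in C3 than in C2, such as Nqo1 (11.9 CPM in C3 against 17.9 in C2 and 17.5 in C1) and Gclm (91.4 against 110 and 115), and 2 were higher, Osgin1 (21.6 against 16.5 and 14.9) and Gsr (182 against 172 and 171).

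The first pattern is the ER stress list, highest in C2, set against the hypoxia list, highest in C3. A set of 20 further ATF4 targets of the amino acid response had 20 of 20 genes higher in C2. Its median log2 ratio of C2 to C3 was 0.24. That of 10 ER chaperones was -0.11, with 0 of 10 higher in C2, which argues against an induction of chaperones as the source. Neither set separates an amino acid response from an unfolded protein response that acts through ATF4, so the latter stays open. A set of 15 further HIF targets had a median log2 ratio of C3 to C2 of 0.16, with 15 of 15 higher in C3. The 10 ER chaperones were also higher in C3, in 10 of 10 cases with a median of 0.11. Relative to each gene's mean, 11 of 29 lists lay above the central range of matched random lists in C3, and 2 lay below it. Lists outside hypoxia rose there too, such as collagen processing (0.12) and epithelial genes (0.10). The HIF set therefore cannot separate a HIF response from this broader rise in C3. After removal of trends with GC content and transcript length the hypoxia list kept a ratio of 0.32 (0.34 before) and the ER stress list 0.32 (0.26 before), so these trends do not account for it. A candidate explanation, if the libraries are separate cultures, is a difference in nutrient or oxygen supply at lysis, for example through cell density. No source says whether they are, and technical sources other than GC content and length were not tested. Culture records or batches that would decide between these were not used here.

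The second pattern is that Mt1 (25.6 CPM in C3 against 46.5 in C1 and 43.7 in C2), Mt2 and the zinc exporter Slc30a1 (10.8 against 19.9 and 22.3) were lowest in C3, where the zinc importer Slc39a10 was highest. Of these, Mt2 and Slc39a10 passed the edgeR test, and Mt1 and Slc30a1 did not (adjusted p = 0.0603 and 0.0683). The median C3 deviation of Mt1, Mt2 and Slc30a1 was -0.60, and -0.58 after correction for GC content and length. Removing these trends thus left the median almost unchanged. The median rests on the middle gene of the set, so it cannot exclude poor recovery of short transcripts for each gene. NRF2 targets had a median C3 deviation of -0.12, below all matched random lists but short of the bound set for it, so an antioxidant response stays open as a contributor. Metallothioneins and Slc30a1 are induced by zinc through MTF-1, so lower available zinc in C3 may explain the set, but these genes were chosen for the pattern and no independent set tested it.

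The third pattern is in C1 alone: Lyz2 (166 counts) and Lpl (5.67 CPM against 1.78 in C2 and 2.31 in C3) were highest there, with Emr1, Csf1r and Xist. Of the leukocyte list, Cd68, Itgam, Laptm5 and Tyrobp were also highest there, and Ptprc was lowest (1, 8 and 13 counts). After thinning all libraries to the depth of C1, both Lyz2 and Lpl stayed above the Poisson interval from the other libraries (Lyz2 at 166 counts against an upper limit of the mean of 66.3, Lpl at 100 against 50.3). They were chosen for the pattern, but both also varied more than counting noise allows when adjusted over all genes tested (Poisson dispersion test, adjusted p = 2.58e-28 and 5.34e-18), which argues against lower depth, acting through counting noise, as the cause for these genes. Of 10 further macrophage transcripts under 20 CPM and with at least 10 counts in all, 6 were highest in C1, with a median log2 ratio to the other libraries of 0.57. Mpeg1 (3.23 CPM against 0.955 and 1.32), C1qb (1.42 against 0.418 and 0.210) and Apoe (12.5 against 6.18 and 7.19) were higher, while Cd74 (4.65 against 4.91 and 5.67), Cd14 (5.33 against 6.04 and 7.21) and C1qa (0.113 against 0.149 and 0.147) were not. C1qa rests on only 2, 10 and 7 counts in C1, C2 and C3. Cd52, below the floor of 10 counts with 3, 3 and 2, was highest in C1 (0.170 CPM against 0.0448 and 0.0420). A trace of macrophage RNA in C1, from cells or from another library on the same run, may be present, but the transcripts went both ways, with Cd74 (82 counts in C1) and Cd14 (94 counts) lowest there, and the share highest in C1 fell between the bounds set for it, so this stays open; the table holds no value for reads shared between libraries.

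The microRNA rows called without C3 were not called by the edgeR F test on all libraries: mmu-mir-689-2 stood at 138 CPM in C1, 224 in C2 and 171 in C3 (adjusted p = 0.0576), and mmu-mir-2134-4 at 54.5, 83.0 and 66.5 CPM (adjusted p = 0.156). MicroRNA rows took 0.0774%, 0.104% and 0.0880% of the counts of C1, C2 and C3. The libraries were made with a poly(A) kit, so counts on these rows need not measure mature microRNAs.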
